A study of Homo sapiens with 6 samples.

How the data were processed

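Total RNA of U251 glioblastoma cells was sequenced in 6 libraries, 3 from cells with an ETV6 hairpin and 3 from cells with a non-specific control (NC) hairpin. Per the labels' protocols, RNA was column-purified with DNase digestion and libraries were made from total RNA with a strand-preserving SMARTer kit. The sample titles speak of a hairpin, whereas part of the protocol text speaks of a small interfering RNA; the titles were followed. Per the submitters' processing notes, HISAT2 and hg38 were used, with no version of HISAT2 given. The gene counter, its strand setting, the gene annotation, the normalization and the statistical tool are not given in the sources used here.

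A single table was used, and each of its genes has a symbol and 3 values. Per the file headers, the deposited fold changes are on a log2 scale, ETV6 over NC. Per the file headers, the deposited table also gives the authors' unadjusted p-value and an adjusted p-value for each gene. The method of adjustment is not stated. The deposited adjusted p-values behave as a Benjamini-Hochberg adjustment over 18625 genes, of which 1056 are not analysed here. Values per library or per group were not used here, so depth is unknown, no library could be compared with another, and no new test between libraries was run. The direction of change was taken from the column header and from the fall of ETV6.

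The table holds 17569 genes, of which 25 carry symbols that a spreadsheet turned into dates, 5 of them called, and these were not named, although the fold change of 1 of them (log2 1.53) lies among the 12 largest rises. Some genes that the rule below takes are not reported here. The fold changes of genes with little data look shrunken: 2395 genes share their fold change and p-value with another gene, in 265 groups, so a fold change near 0 can also mean little data. The standard error given here as implied is the deposited log2 fold change divided by the normal quantile of the authors' two-sided p-value, which holds if the authors' test was a Wald test and is otherwise only a scale. Its median was 0.14 and its largest value 0.26. Symbols were matched to GENCODE 29 on GRCh38 for coordinates, gene type, length of the longest transcript and GC content, which succeeded for 16817 genes (95.7%). Length and GC trends were fitted over the 14618 matched genes that share their values with no other gene.

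Genes were called at an authors' adjusted p under 0.05. The 33 gene lists were fixed before the data were examined. Lists with at least 5 measured members were tested with cameraPR of limma 3.58.1 (R 4.3.3) on signed normal quantiles of the authors' p-values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Two-sided Fisher's exact tests compared called with uncalled members against all other genes, also with Benjamini-Hochberg adjustment over lists. The genes compared include the 2395 that share their values, of which 4 were called. A list with few such genes can therefore stand out in the exact tests for that reason alone. The exact tests were not repeated with trends removed. For each list the members were counted by the authors' adjusted p over all genes and by a Benjamini-Hochberg adjustment of the authors' p-values over the list alone. In 6 uncalled lists the sign of the median, the mean and the test were not the same: Ras-MAPK components, ERK output genes, p53 targets, extracellular matrix, mesenchymal transition and immune markers. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

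The rule for named genes took ETV6, the 12 largest rises and 12 largest falls past the threshold among genes with a usable symbol, and up to 4 called members of each list with the smallest authors' adjusted p. The rule also asked for a minimum level, for consistent libraries, for the most abundant members of lists with few calls and for the 5 called genes with the highest level; these parts need levels and could not be applied. LDHA, PMVK, E2F2, IL11 and FABP7 fall outside the rule and were named after their values were seen. The same holds for CES1P1, ADM and the glycolytic enzymes named beside LDHA. The plan had also foreseen tests on values per library, or a direction read from group levels, and this table holds neither.

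Length and GC trends were removed with natural splines of 4 degrees of freedom, fitted to the log2 fold change for single genes and medians and to the signed normal quantile for list tests. The list test was tested on simulated data, made by shuffling the normal quantiles over the 17569 genes. A shift of 1 in the normal quantile was found in 26% of shifted lists and a shift of 2 in 95.5%, while 0.36% of unshifted lists were called at either size. Shuffling removes any correlation between genes, so the rate of false calls for lists of co-regulated genes is unknown. A simulated length trend alone over 14618 genes called the ribosomal protein list in 20% of simulations, and in 0% once the trend was removed. The same spline on the same lengths made and removed this trend, so the 0% was nearly fixed in advance. It does not show that removal is complete in the real data. Alternatives covered stricter thresholds, a minimum fold change, other adjustments, centring, other list statistics and correlations, and the removal of trends or of genes with shared values.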

Results

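RNA sequencing was used to measure gene expression in U251 cells, an established human glioblastoma line, that carried a short hairpin RNA (shRNA) against ETV6 or a non-specific control (NC) hairpin. The labels name 6 libraries, 3 with the ETV6 hairpin and 3 with the control hairpin. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The values described here are those of the authors' deposited table, which gives a log2 fold change, a p-value and an adjusted p for 17569 genes and no value per library. Depth per library is therefore unknown, and no interval that needs counts is given. The comparison addresses which transcripts differ in glioblastoma cells when ETV6, a transcription factor of the ETS family best known as a repressor, is targeted.

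The targeted gene was lower in the knockdown. ETV6 (chromosome 12, 11649854 to 11895402, GRCh38, protein coding) had a log2 fold change of -1.62 in the authors' deposited table, with an implied standard error of 0.17 and an authors' adjusted p of 1.68e-18. Taken at face value, this is a 3.08-fold lower level, with 32.5% of the control level remaining. Sizes of change given here and below are those of the deposited values. These look shrunken for genes with little data, so they may understate changes. The sign of the fold changes rests on the column header and on the fall of ETV6, since no group levels accompany them.

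The largest change was a rise of the liver-type carboxylesterase CES1, and the largest fall was that of GFAP, the intermediate filament of astrocytes. CES1 (chromosome 16, 55802851 to 55833337) was 52.9-fold higher, with a log2 fold change of 5.73, an implied standard error of 0.20 and an authors' adjusted p of 2.84e-171 in the authors' deposited table. GFAP (chromosome 17, 44903161 to 44916937) was 10.1-fold lower, with a log2 fold change of -3.34, an implied standard error of 0.11 and an authors' adjusted p of 9.17e-184 in that table. Carbonic anhydrase 9 (CA9; chromosome 9, 35673856 to 35681159), a classical target of the hypoxia response, was 6.21-fold lower in the authors' deposited table (log2 fold change -2.63, implied standard error 0.21). ROBO4 (chromosome 11, 124883691 to 124898500), a guidance receptor of endothelial cells, was 5.44-fold higher in the same authors' deposited table (log2 fold change 2.44, implied standard error 0.15).

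Further large rises in the authors' deposited table were those of the iron-binding protein lactoferrin (LTF, log2 fold change 2.07), the actin-bundling protein LCP1 (2.06) and ARHGDIB (2.05). The export pump ABCC2 (1.95), the matrix protease MMP3 (1.62) and the Ras exchange factor RASGRF1 (1.61) followed in the authors' deposited table. HLA-B, a class I antigen-presenting molecule (1.57), the endothelial receptor kinase TIE1 (1.54) and the adhesion molecule ICAM1 (1.52) complete the rises listed from the authors' deposited table. The pseudogene CES1P2 also rose (2.20 in the authors' deposited table), whereas the pseudogene CES1P1 did not pass (0.35, authors' adjusted p 0.148). How any reads shared between CES1 and its pseudogenes were assigned is not given in the sources used here. The value of CES1P2 and, to an unknown degree, that of CES1 are therefore uncertain. Further large falls in the authors' deposited table were those of the neuropeptide Y receptor NPY1R (-1.88), the ephrin receptor EPHA3 (-1.78) and the corepressor HR (-1.76). The acetyl-group receptor FIBCD1 (-1.65), the calcification inhibitor MGP (-1.57) and the anchoring protein AKAP6 (-1.52) also fell in the authors' deposited table. The long non-coding RNA LINC00461 (-1.51), the membrane glycoprotein GPM6B (-1.44) and the zinc finger factor ZNF423 (-1.43) complete the falls listed from the authors' deposited table. These changes were not equally well measured. The implied standard errors of RASGRF1 (0.25), TIE1 (0.26), CES1P2 (0.26) and GPM6B (0.26) lay near the largest of all genes. Those of HLA-B (0.12) and MMP3 (0.13) were smaller.

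In all, 2873 genes had an authors' adjusted p under 0.05, which is 16.4% of the genes in the authors' deposited table. Of these, 1386 were higher and 1487 were lower in the knockdown, and their median absolute log2 fold change was 0.49, or 1.41-fold. Most changes were small as deposited: 1475 of the called genes (51.3%) had an absolute log2 fold change under 0.5 in the authors' deposited table. With an absolute log2 fold change of at least 1 also required, 144 genes remained, 80 higher and 64 lower. Shrinkage of the fold changes may have contributed to both counts. Fold changes followed transcript length, with a Spearman correlation of -0.38 across 14618 genes, which are not independent replicates. In the decile of shortest transcripts 280 genes rose and 22 fell, and in the decile of longest transcripts 50 rose and 380 fell.

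**Figure D1:**
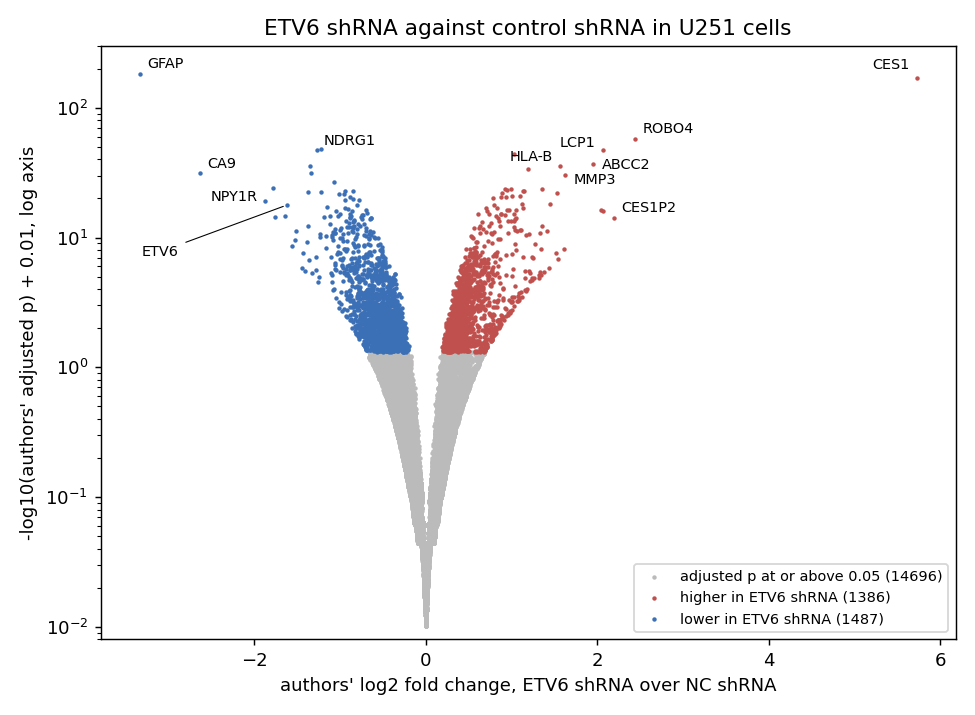
Each point is a gene of the authors' deposited table, with the authors' log2 fold change (ETV6 shRNA over NC shRNA) on the horizontal axis and -log10 of the authors' adjusted p, plus 0.01, on a logarithmic vertical axis. Red points mark the 1386 genes that were higher and blue points the 1487 that were lower at an authors' adjusted p under 0.05, with CES1 farthest to the right at 5.73 and GFAP farthest to the left at -3.34.

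Of 33 gene lists fixed before the data were examined, 32 had enough measured members to be tested, and 12 differed from the other genes as a group at an adjusted p under 0.05 (limma cameraPR, preset correlation 0.01, Benjamini-Hochberg over lists). Of these, 5 lay towards higher and 7 towards lower expression. An estimated correlation between genes needs values per library and was not used here. With smooth trends of transcript length and GC content removed, 9 of the 12 lists were still called.

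The list of hypoxia and glycolysis genes fell most clearly. Of 33 measured members, 18 fell, 1 rose and 14 did not pass the threshold, with a median log2 fold change of -0.36 and 22 falls and 1 rise when adjusted over the list alone. The falls included NDRG1 (-1.27 in the authors' deposited table, implied standard error 0.08), CA9, the glucose transporter SLC2A1 (-0.84) and the angiogenic factor VEGFA (-0.70). LDHA, the lactate-producing dehydrogenase, was the member that rose, with a log2 fold change of 0.44 in the authors' deposited table. Among other glycolytic enzymes HK2 (-0.50), PFKP (-0.45), ENO1 (-0.32) and PGK1 (-0.24) fell in the authors' deposited table. The enzymes HK1, ALDOA (-0.19), ALDOC, GAPDH (-0.14), TPI1, PGAM1 (0.15), ENO2 and PKM did not pass in that table. The member ADM (0.01) did not pass there either. The list's adjusted p was 5.09e-16 (limma cameraPR with Benjamini-Hochberg adjustment).

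Genes of cholesterol and fatty acid synthesis also fell. Among 27 measured members 14 fell and 1 rose, with 17 falls and 1 rise adjusted over the list alone, and the median log2 fold change was -0.31. SCD (-0.78), FASN (-0.75), HMGCS1 (-1.09) and the sterol sensor partner INSIG1 (-0.67) were among the falls in the authors' deposited table. PMVK, a kinase of the mevalonate pathway, was the member that rose (0.51 in the authors' deposited table). The adjusted p of the list was 8.95e-08 (limma cameraPR with Benjamini-Hochberg adjustment).

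The lists of astrocyte and of neural progenitor markers lay towards lower expression, although not all of their members did. Of the astrocyte markers 6 had a log2 fold change below 0 and 5 above 0. Of the progenitor markers 15 lay below 0 and 8 above 0. Of 11 measured astrocyte markers, 5 fell and none rose, with the same counts adjusted over the list alone, and the median log2 fold change was -0.37 (limma cameraPR adjusted p = 1.31e-10). Beside GFAP, the glutamate transporter SLC1A3 (-1.08), the glial transcription factor SOX9 (-0.52), the gap junction protein GJA1 (-0.64) and the fatty acid binding protein FABP7 (-0.88) fell in the authors' deposited table. In a rank-based test, where the size of the GFAP fall carries no extra weight, the astrocyte list was not called (limma cameraPR adjusted p = 0.0970). Of 23 measured proneural and progenitor markers, 6 fell and none rose, also when adjusted over the list alone, with a median of -0.28 (limma cameraPR adjusted p = 0.00108). The intermediate filament nestin (NES, -0.84), SOX4 (-0.73), SOX9 and the growth factor receptor PDGFRA (-0.79) led these falls in the authors' deposited table, SOX9 being a member of both lists. Of 27 measured glioblastoma mesenchymal markers, 5 rose and 2 fell (5 and 3 adjusted over the list alone), with RELB (1.11) and EMP3 (0.76) among the rises in the authors' deposited table, and the list was not called (limma cameraPR adjusted p = 0.220).

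Cytosolic ribosomal protein genes rose by small amounts. Of 46 members 24 rose and none fell, 28 rose adjusted over the list alone, and the median log2 fold change was 0.21 (limma cameraPR adjusted p = 7.83e-13). RPS3A (0.54), RPSA (0.51), RPS27 (0.43) and RPL35 (0.42) were those with the smallest authors' adjusted p in the authors' deposited table. These are short transcripts, with a median length of 1170.5 bases, and with the length and GC trends removed the list's median log2 fold change was 0.11, 14 members rose and 2 fell, and the list was still called (limma cameraPR adjusted p = 1.02e-05).

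Matrix proteases and their inhibitors were shifted upwards, whereas integrins were shifted downwards. Among 36 measured proteases and inhibitors 10 rose and 3 fell, with the same counts adjusted over the list alone and a median of 0.15 (limma cameraPR adjusted p = 7.24e-04). The collagenase MMP1 (1.41), MMP3, ADAMTS1 (1.02) and ADAMTS4 (1.03) rose in the authors' deposited table. A rank-based test did not call the list (limma cameraPR adjusted p = 0.120). Of 19 measured integrin genes, 8 fell and 1 rose, also when adjusted over the list alone, with a median of -0.12 (limma cameraPR adjusted p = 0.00197). ITGA7 (-1.12), ITGB8 (-1.28) and ITGB3 (-0.63) fell and the fibronectin receptor subunit ITGA5 rose (0.58) in the authors' deposited table. The integrin call ended with the length and GC trends removed (limma cameraPR adjusted p = 0.111), where 4 members fell and 2 rose. Genes of the extracellular matrix moved both ways, with 7 rises and 12 falls among 51 measured members (8 and 12 adjusted over the list alone), and were not called as a group (limma cameraPR adjusted p = 0.623). A two-sided Fisher's exact test for change in either direction gave this list a Benjamini-Hochberg adjusted p of 0.00234. With the length and GC trends removed 12 of its genes rose and 9 fell. Here COL6A3 (1.13) and COL4A1 (0.71) rose while COL18A1 (-1.37) and COL12A1 (-0.87) fell in the authors' deposited table.

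Targets of TGF-beta and YAP signalling also moved both ways, with more falls. Of 29 members 9 fell and 6 rose, 12 and 6 adjusted over the list alone, with a median of -0.14 (limma cameraPR adjusted p = 0.00562). PMEPA1 (-1.02), the differentiation inhibitor ID3 (-0.96) and the matricellular factor CTGF (-0.69) fell, and the receptor kinase AXL rose (0.61), in the authors' deposited table. The call ended in a rank-based test (limma cameraPR adjusted p = 0.152), with the log2 fold change as the statistic (0.114) and with a preset correlation of 0.05 (0.0747).

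Among 27 measured genes of NF-kB signalling and inflammatory cytokines 6 rose and 2 fell, with the same counts adjusted over the list alone and a median of 0.13 (limma cameraPR adjusted p = 0.0203). The NF-kB subunit RELB, ICAM1 and the cytokine IL1A (1.43) rose, and the cytokines LIF (-0.72) and IL11 (-0.54) fell, in the authors' deposited table. The call ended with a preset correlation of 0.05 (limma cameraPR adjusted p = 0.133), in a rank-based test (0.0835) and with the length and GC trends removed (0.146). Of 43 measured interferon-stimulated genes 7 rose and none fell, also adjusted over the list alone, and the list was not called (limma cameraPR adjusted p = 0.0786). The antiviral enzyme OAS3 (0.75), IFI35 (0.64) and IFITM3 (0.57) were among those rises in the authors' deposited table, and 4 members rose with the length and GC trends removed.

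Cell cycle genes were shifted upwards. Of 44 members 12 rose and 2 fell, with the same counts adjusted over the list alone and a median of 0.09 (limma cameraPR adjusted p = 0.0124). The phosphatase CDC25A (0.88), survivin (BIRC5, 0.57) and CDK2 (0.55) rose, while the proliferation marker MKI67 (-0.49) and the transcription factor E2F2 (-0.70) fell, in the authors' deposited table. The call ended with a preset correlation of 0.05 (limma cameraPR adjusted p = 0.137), with the log2 fold change as the statistic (0.153) and in a rank-based test (0.120), and with the length and GC trends removed 8 members rose and 3 fell. Of 38 measured apoptosis regulators 5 rose and 2 fell (6 and 2 adjusted over the list alone; 5 and 0 with the trends removed), with the pore-forming protein BAK1 at 0.46 in the authors' deposited table, and the list was not called (limma cameraPR adjusted p = 0.268). Of 27 p53 target genes 3 rose and 3 fell, also adjusted over the list alone (4 and 2 with the trends removed), with GADD45A (0.59) and PLK2 (0.57) higher and MDM2 (-0.88) lower in the authors' deposited table (limma cameraPR adjusted p = 0.726).

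The endothelial markers were called as a list towards higher expression (limma cameraPR adjusted p = 4.82e-05), but only ROBO4 and the VEGF receptor KDR (0.89 in the authors' deposited table) rose among 9 measured members, also adjusted over the list alone. The median of these markers was 0.10, and a rank-based test did not call the list (limma cameraPR adjusted p = 0.228). Among markers of other cell types that were not called as lists, the lysosomal protein CD68 (1.13) rose as the sole immune marker of 11 measured, and the tight junction protein CLDN4 (1.01) as the sole epithelial marker of 9, in the authors' deposited table. Of 11 measured neuronal markers the neurofilament NEFL (-0.80) and SYT1 (-0.74) fell, and of 8 oligodendrocyte markers CNP (0.26) rose, in the authors' deposited table. The counts for these 4 lists were the same adjusted over the list alone, and their adjusted p values were 0.428, 0.542, 0.0786 and 0.543 in the same order (limma cameraPR).

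Components of PI3K-AKT-mTOR signalling changed individually and were not called as a group (limma cameraPR adjusted p = 0.0786). Of 37 members 8 fell and 5 rose, 11 and 5 adjusted over the list alone, and a two-sided Fisher's exact test for change in either direction gave a Benjamini-Hochberg adjusted p of 0.0200. With the length and GC trends removed 4 fell and 4 rose, and the median log2 fold change was -0.04 in place of -0.17. The mTOR inhibitor DDIT4 (-0.65) fell, and SGK1 (0.53) and MTOR (0.31) rose, in the authors' deposited table. Of 41 Ras-MAPK components 5 rose and 6 fell (6 and 9 adjusted over the list alone), 6 rose and 2 fell with the trends removed, and the list was not called (limma cameraPR adjusted p = 0.767). RASGRF1, RRAS (0.77), the adaptor SHC1 (0.40) and RASSF1 (0.48) rose in the authors' deposited table. ERK output genes gave 5 rises and 3 falls among 25 members (5 and 4 adjusted over the list alone; limma cameraPR adjusted p = 0.767), with the phosphatase DUSP5 (0.85) higher and cyclin D1 (CCND1, -0.64) lower in the authors' deposited table. Of 37 measured receptor tyrosine kinases 6 rose and 8 fell, also adjusted over the list alone, with EPHA3 and DDR1 (-0.81) lower and KDR and AXL higher in the authors' deposited table. This list was not called in a common direction (limma cameraPR adjusted p = 0.585), and the exact test for change in either direction gave a Benjamini-Hochberg adjusted p of 0.00724. Growth factors and ligands gave 3 rises and 6 falls among 32 measured members (3 and 7 adjusted over the list alone, 3 and 4 with the trends removed; limma cameraPR adjusted p = 0.287), with PDGFD (-1.28) and PDGFB (-0.92) lower and FGF1 (1.38) higher in the authors' deposited table.

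The RNA interference machinery was called towards lower expression (limma cameraPR adjusted p = 0.0264). Of 13 members DICER1 (-0.92), TNRC6A (-0.57) and TNRC6C (-0.42) fell in the authors' deposited table and none rose, with 4 falls adjusted over the list alone. These transcripts are long, with a median length of 8438 bases over the list. The call ended with a preset correlation of 0.05 (limma cameraPR adjusted p = 0.0989), with the log2 fold change as the statistic (0.0546) and with the length and GC trends removed (0.326). Trend removal moved the list's median from -0.21 to -0.02, and TNRC6C no longer passed.

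The remaining lists were not called, with limma cameraPR adjusted p values of 0.287 to 0.920. Of 23 measured ETS family genes 2 rose and 4 fell, also adjusted over the list alone, but 3 rose and 1 fell with the length and GC trends removed. ETV6, the target of the hairpin, is a member of this list and was the fall left with the trends removed. Apart from ETV6, the gene of this list with the smallest authors' adjusted p was ETS2 (0.38 in the authors' deposited table). Of 33 genes of the integrated stress and unfolded protein response 4 rose and 8 fell (5 and 10 adjusted over the list alone), with DDIT3 at 0.53 and SLC7A11 at -0.83 in the authors' deposited table, and the exact test for change in either direction gave a Benjamini-Hochberg adjusted p of 0.0226. With the length and GC trends removed 1 of these genes rose and 6 fell. Of 19 measured genes of mesenchymal transition smooth muscle actin (ACTA2, 1.20) rose, and PRRX1 (-1.0) and CDH2 fell, in the authors' deposited table, where CDH2 no longer passed with the length and GC trends removed. Of 23 measured Wnt targets and regulators the Wnt receptor FZD2 (0.87) and DKK3 (0.38) rose, and the Wnt inhibitor DKK1 (-0.94) fell, in the authors' deposited table. HES1 (-0.50) was the sole Notch target or ligand of 16 measured to change in the authors' deposited table. Of 19 genes in the histone list 3 rose and 1 fell, with HIST1H2BK at 1.07 in the authors' deposited table, and the fall was that of H1F0 (-0.51 in the authors' deposited table), which encodes a linker histone that does not depend on replication. For the transition, Wnt, Notch and histone lists the counts were the same adjusted over the list alone. With the trends removed, 2 genes rose and 1 fell in the transition list, and 3 rose and 3 fell in the histone list. None of the 13 mitochondrially encoded genes was measured under the symbols used here.

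**Figure D2:**
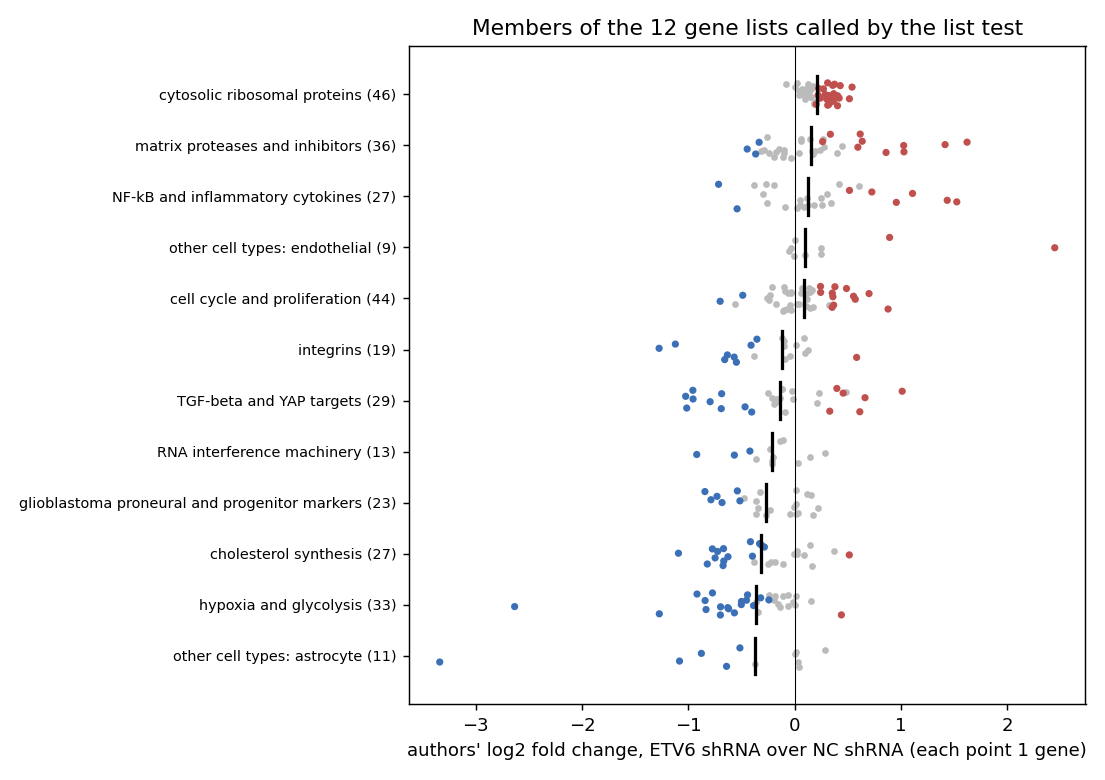
Each point is a measured member of a gene list, placed by its log2 fold change (ETV6 shRNA over NC shRNA) in the authors' deposited table, for the 12 lists called by limma cameraPR, with the number of members in parentheses. Red and blue points rose and fell at an authors' adjusted p under 0.05, grey points did not pass, and the black bars are list medians, which run from -0.37 for the astrocyte markers to 0.21 for the ribosomal proteins.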

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

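The alternatives that leave out genes with shared values, centre on the median of all genes or remove length and GC trends were chosen after the data were seen; the others were fixed before the data were examined. The fall of ETV6 and its call held under every alternative run, at -1.54 with trends removed. The count of 2873 genes moved to 1828 (884 higher, 944 lower) at an authors' adjusted p under 0.01, to 1062 (522 and 540) under 0.001, to 144 (80 and 64) with an absolute log2 fold change of at least 1, to 143 (81 and 62) with that minimum after centring, and to 666 (316 and 350) with Bonferroni adjustment, all by construction. Over the 14618 genes used for trends, 2829 were called before trend removal (1360 higher, 1469 lower) and 2077 after it (1089 and 988), with 1653 called both times in the same direction and none in opposite directions. Adjusting again over the genes held gave 2901 and leaving out shared values 2869. Of the 120 genes that the naming rule takes, not all of which are named in the text, 26 no longer passed with Bonferroni adjustment and 9 with trends removed, and none reversed. None of the 12 called lists reversed; among uncalled lists the direction of the test turned under some alternatives, as for receptor tyrosine kinases, extracellular matrix, ERK output genes and histones with trends removed, with no call in either direction. The 12 called lists became 6 in a rank-based test and 7 with trends removed and a preset correlation of 0.05. Hypoxia, cholesterol synthesis, ribosomal proteins and progenitor markers passed under every alternative run. The limma cameraPR adjusted p rose past 0.05 as follows. With a preset correlation of 0.05 it was 0.137 for cell cycle, 0.133 for NF-kB, 0.0989 for RNA interference and 0.0747 for TGF-beta and YAP targets. With the log2 fold change as the statistic it was 0.153 for cell cycle, 0.0546 for RNA interference and 0.114 for TGF-beta and YAP targets, while histones, not called before, reached 0.0315. In the rank-based test it was 0.120 for cell cycle and for matrix proteases, 0.0835 for NF-kB, 0.0970 for astrocyte markers, 0.228 for endothelial markers and 0.152 for TGF-beta and YAP targets. With trends removed it was 0.111 for integrins, 0.146 for NF-kB and 0.326 for RNA interference. With trends removed and a preset correlation of 0.05 it was 0.269 for cell cycle, 0.270 for integrins, 0.419 for NF-kB, 0.548 for RNA interference and 0.0588 for TGF-beta and YAP targets. The cause was not tested. No paired analysis was possible because the table holds no values per library. For the same reason other tests between libraries, other normalizations, level filters, pseudocounts, leaving out a library, an estimated correlation and other splits of the libraries were not run, and what depth limits is unknown.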

Other observations

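The 4 gene lists described first, the comparison of CES1 with its paralogs, the count on culture conditions and the window test with trends removed were chosen after the results were seen, as was the stricter reading of the test on 7-base words. The p values of the lists are adjusted over these 4 alone, which were picked for their values, so they describe the lists and are too small as tests. Genes of MHC class I antigen presentation lay towards higher expression. Of 20 measured members 11 rose and none fell in the authors' deposited table, with a median log2 fold change of 0.42 (limma cameraPR adjusted p = 1.42e-16, and 1.59e-13 with length and GC trends removed). The members included the class I chains HLA-B (1.57) and HLA-C (0.76), their light chain B2M (0.63) and the peptide transporter TAP1 (1.01) in the authors' deposited table. The immunoproteasome subunits PSMB8 (1.05) and PSMB9 (1.03) and the activator PSME2 (0.87) rose beside them in the authors' deposited table. Reads of HLA genes can be shared between class I copies, so the size of each HLA change is uncertain. The constitutive proteasome gave 14 rises and 1 fall among 31 measured subunits, with a median of 0.24 (limma cameraPR adjusted p = 3.63e-06), and its fall was PSMD1 (-0.56 in the authors' deposited table). With trends removed 5 of these subunits rose, 1 fell and the median was 0.11.

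Subunits of mitochondrial complex I rose in 18 of 36 measured genes and none fell, with a median of 0.34 (limma cameraPR adjusted p = 4.28e-09, and 5.03e-05 with trends removed). NDUFA2 (0.72), NDUFA7 (0.61) and NDUFC2 (0.57) had the largest changes among these rises in the authors' deposited table. These transcripts are short, and with trends removed 12 rose and 1 fell, with a median of 0.22. Clustered protocadherins, adhesion molecules of neural cells, fell in 6 of 36 measured genes and none rose (limma cameraPR adjusted p = 0.00339, 0.00440 with both trends removed and 0.0588 with the length trend alone removed, which ended the call). Their share of called members did not stand apart from other genes (two-sided Fisher's exact test for falls, Benjamini-Hochberg adjusted p = 0.241), while 29 of the 36 had a log2 fold change below 0. The falls included PCDHGB1 (-1.08), PCDHGA9 (-0.76) and PCDHGB2 (-0.65) in the authors' deposited table. Protocadherins of the gamma cluster (PCDHG genes) share exons, so which of the PCDHG genes changed is uncertain.

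The hypoxia and glycolysis list and the ribosomal protein list moved in opposite directions, and fold changes also followed transcript length. With a length trend removed, the limma cameraPR adjusted p was 4.51e-16 for hypoxia and 1.54e-06 for ribosomal proteins. With a GC trend removed it was 2.57e-16 and 1.03e-09. For the ribosomal proteins this does not decide whether length was the whole cause. Length was that of the longest annotated transcript, which may not be the one expressed, so trend removal may be incomplete. For hypoxia and glycolysis the median log2 fold change was -0.36 before and -0.38 after removal of both trends, with 18 and 19 falls. These values argue against the trends as a source of that fall. For the ribosomal proteins the median log2 fold change was 0.11 with both trends removed, so part or all of that rise may come from the trends. A difference in cell density or oxygen between dishes cannot be told apart from an effect of the knockdown on the 18 hypoxia and glycolysis genes that fell, since the table gives no value per dish. An effect of ETV6 loss on this group is a hypothesis that remains open.

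CES1 rose far more than any other gene. The highest other carboxylesterase gene or pseudogene, CES1P2, stood at 2.20 in the authors' deposited table, below CES1 by 3.53 with an implied standard error of 0.33. The pseudogene CES1P1 stood at 0.35 there and did not pass. CES1 was picked because it had the largest rise, so the gap to CES1P2 does not decide whether shared reads contributed to either change. That remains open. The median log2 fold change of 14 genes within 1 Mb was 0.0764 (95% bootstrap interval -0.09 to 0.22). Carboxylesterase genes and pseudogenes, among them the nearby CES1P2, and genes with shared values were left out of this median. It argues against a gain of the wider region, but a gain limited to CES1 and CES1P2 remains open. A rise of CES1 in few cells or a single library remains open without values per library.

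Calls ran across the genome, and a difference in copy number between cell populations or an off-target effect of the hairpin may contribute. Of windows of 25 adjacent genes, 291 had an absolute median log2 fold change of at least 0.25 against at most 39 in 100 shuffles, but with length and GC trends removed 1 did, against at most 13. A gain of 0.25 planted on 211 genes of chromosome 16 was found in 100% of simulations after trend removal. It was planted in shuffled fold changes, which carry no length or GC trend. The simulation therefore cannot show that trend removal would spare a real gain, and it covered no smaller region. No excess of windows was left with the trends removed, but regional copy number remains open. Among 7-base words in 3' UTRs of 13627 genes, the most negative statistic after trend removal was -4.84, for CGGCGGC in 277 genes, and 1 of 100 shuffles was as low, at -4.99. This met the limit set beforehand for the absence of a seed-like effect, which asked only that the word lie within the range of the shuffles. The word lies so close to the edge of that range that a seed-like effect was left open. An effect of the hairpin on other transcripts remains open because a single hairpin comparison was analysed here.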
